A study of Homo sapiens with 6 samples.

How the data were processed

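HiChIP, which combines chromosome conformation capture with immunoprecipitation to find DNA contacts held at a chosen chromatin protein or histone mark, was analysed in 6 libraries of the G401 cell line. G401 is an established human rhabdoid tumour line that lacks SMARCB1, a core subunit of the SWI/SNF chromatin remodelling complex. Per the labels, the line used here carried a doxycycline-inducible SMARCB1, and doxycycline at 1 μg/ml switched it on. The libraries formed 3 groups of 2: H3K27ac, a histone mark of active enhancers and promoters, at day 0 without SMARCB1; H3K27ac at day 3 of re-expression; and ARID1A, a SWI/SNF subunit, at day 3. Groups and replicate numbers were taken from the sample titles. Between day 0 and day 3, SMARCB1, doxycycline and time in culture changed together. No group had doxycycline without SMARCB1 re-expression, so their effects cannot be told apart. No label says that replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

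Per the labels' protocols, the libraries were sequenced as paired reads of 150 bp. HiC-Pro, Bowtie2 and the hg19 build are named in the submitters' processing notes, without versions. The settings, the way anchors were called and the loop caller are not given in the sources used here. Each deposited file lists pairs of anchors with a whole-number count of paired-end tags (PETs) joining them and a value between 0 and 1. The deposited counts are raw and not normalised. The deposited value from 0 to 1 has no header, so whether it is a p-value or a q-value is not stated, and it was used only as a threshold of 0.01 in alternatives. All listed loops joined anchors on the same chromosome and spanned 5 kb to 2000 kb, and the lowest PET count listed was 1. Coordinates are printed as the files give them, and the files do not state whether they count from 0 or 1.

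The files held between 44104 and 164053 loops and between 253502 and 982141 PETs per library. Replicates of a group shared 98.4% to 99.7% of their anchors base for base, taking the smaller list as the base, while libraries of different groups shared 1.74% to 3.48%. Anchors therefore appear to have been called per group. A region without an anchor in a group was not measured there, and its unlisted loops are not evidence of 0 contacts, so no fold is given for it.

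To compare groups, anchors of all 6 files that overlapped by 1 bp or more were merged with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6. The 51970 distinct anchors became 30001 consensus anchors with a median width of 6077 bp and a longest width of 115607 bp. PETs of loops joining the same pair of consensus anchors were summed, giving 348566 consensus loops, and an unlisted loop entered as 0. Loops inside a single consensus anchor were left out. They held 13.7% and 13.3% of the PETs in the day 0 libraries, 6.30% and 6.26% in the day 3 H3K27ac libraries, and 3.55% and 3.53% in the ARID1A libraries. Cytoband names come from the hg19 band table in circlize 0.4.16. No gene annotation of hg19 was used here, so regions are named by position and band, and the planned tests on promoters, genes and gene lists were not run. Chromosome Y was left out of the counts by band and by chromosome.

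PET counts per loop and per anchor were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with the 4 libraries of the compared groups. Library sizes were the PETs of each library within the tested set, adjusted by TMM; with anchors called in both groups the TMM factors lay near 1, so folds there differ from ratios of CPM mainly through these library sizes. Loops needed 4 or more PETs and anchors 10 or more PETs in at least 2 libraries. Calls had a Benjamini-Hochberg adjusted p under 0.05. The same tests were repeated on loops whose anchors were both called in each of the groups compared, and on anchors called in both with PETs summed over those loops. This set was chosen after the data were examined, and it is the only one for which folds are given. Folds are given on the log2 scale with the standard error of the fit. Values in CPM are counts of PETs scaled to a common total by the consensus PETs of each library, without TMM. For a region with no anchor in a group, the 0 entered there is set by anchor calling, so its call and its place among the named regions test no change in contacts. Named regions follow a rule fixed before the data were examined: per comparison and direction, the 12 anchors and 4 loops with the smallest p among calls whose libraries do not overlap between groups on CPM, ties by larger fold. The same rule was applied again within the set with anchors in both groups.

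Values per library were compared with exact permutation tests, two-sided, over 6 arrangements, which cannot give a p below 0.333. Shares of loops or anchors carry 95% Wilson intervals and were compared with Fisher's exact test in scipy 1.17.1; loops and anchors are not replicates, and such tests and intervals cover counting error only. Listing of H3K27ac loops in the ARID1A libraries was also compared within 12 strata of PET number and span, as a Mantel-Haenszel odds ratio, and within finer strata of day 3 PETs, which were chosen after the data were examined.

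The fit was tested on simulated data, drawn from the means and library sizes of each comparison, with 200 of the tested loops or anchors changed. For day 3 against day 0 H3K27ac, 6% of 2-fold and 36% of 4-fold changes were recovered among 37920 loops, and 53% and 93% among 15046 anchors. For ARID1A against H3K27ac, the shares were 2% and 12% among 47562 loops and 43% and 88% among 22850 anchors. With anchors called in both groups, 11% and 55% were recovered among 16642 loops and 76% and 96% among 6251 anchors for day 3 against day 0. For ARID1A against H3K27ac on such anchors, 3% and 25% were recovered among 28338 loops and 63% and 92% among 11052 anchors. Between 0 and 8 unchanged loops or anchors were called per simulation. In these simulations most 2-fold changes of single loops went undetected, and a larger share was recovered for anchors. Far more loops and anchors were called in the data than the 200 changed here, which makes the adjusted threshold less strict there. Each anchor was also drawn independently, although real anchors share loops. The shares therefore do not give the power in the data, nor show which level is more reliable.

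Replicates were compared before they were averaged. Per loop, the day 3 H3K27ac libraries differed by no more than counting noise (chi-square over degrees of freedom 0.998, p = 0.577), while the day 0 libraries (1.07, p = 0.000684) and the ARID1A libraries (1.03, p = 0.0268) differed slightly more. Over 7 classes of span the day 3 H3K27ac libraries did differ (chi-square over degrees of freedom 38.5), so they were kept as 2 libraries, and the test with both summed as 1 is an alternative. The day 0 libraries differed over these classes too (4.91), and the ARID1A libraries hardly (1.03). Over windows of 1 Mb the ratio was 1.36 for day 0 (chi-square p = 2.68e-14), 1.07 for day 3 H3K27ac and 1.08 for ARID1A. Day 0 replicates thus differed by region beyond counting noise. The biological coefficient of variation of the fits over all regions lay between 0.00988 and 0.0236, which is close to counting noise. These fits pooled the spread over all tested loops or anchors, with median degrees of freedom of 30092 to 95124. Very small p from 2 libraries against 2 therefore rest on this pooled spread, and the simulations drew their counts at the dispersion of their own fit.

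The alternatives fixed before the data were examined were DESeq2 size factors, library totals without TMM, DESeq2 1.42.0, no filter, a stricter filter (10 PETs per loop, 25 per anchor), all 6 libraries in the fit, the replicate number as a block, random thinning to the smallest library (253502 PETs, or 219827 between consensus anchors for the fits), loops at the deposited value of 0.01 or less, loops listed in every library, fixed bins of 10 kb and leaving out each library. Added after the data were examined were anchors called in both groups, in all 3 groups, of similar width (within 0.2 on the log2 scale), or overlapping reciprocally by 90%, the day 3 H3K27ac libraries summed, the newer quasi-likelihood method of edgeR, and thinning together with library totals.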

Results

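Contacts between distant DNA segments were measured by HiChIP in the rhabdoid tumour cell line G401, before and 3 days after SMARCB1 was switched on again. There were 2 libraries for H3K27ac at day 0, 2 for H3K27ac at day 3 and 2 for the SWI/SNF subunit ARID1A at day 3. The day 0 H3K27ac libraries listed 46677 and 44104 loops holding 301703 and 253502 PETs. The day 3 H3K27ac libraries listed 162010 and 162167 loops with 929128 and 982141 PETs, and the ARID1A libraries 157578 and 164053 loops with 435210 and 467487 PETs. A loop is a pair of regions, called anchors, on the same chromosome, and its PET count is the number of paired-end tags that joined them.

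The first comparison asked whether the H3K27ac contact landscape was larger at day 3 of SMARCB1 re-expression than at day 0. H3K27ac loops numbered 45390.5 ± 1819 per library at day 0 and 162088 ± 111 at day 3 (SD, n = 2 each), a ratio of 3.57. Anchors numbered 8576 ± 25.5 at day 0, covering 63.1 and 62.9 Mb, and 17370 ± 9.90 at day 3, covering 130.9 and 131.0 Mb. Replicates of a group list nearly the same anchors, apparently called once per group. Neither the SD of anchor number nor a test of it over libraries therefore measures spread between replicates. PETs per loop were 6.11 ± 0.506 and 5.90 ± 0.227, but 5.79 ± 0.0551 and 2.99 ± 0.0392 with every library thinned to the same number of PETs. The PET-weighted median span was 77.6 ± 1.75 kb at day 0 and 100.5 ± 0.870 kb at day 3, and contacts over 100 kb made up 43.4% ± 0.544 and 50.1% ± 0.253 of PETs. The exact two-sided permutation p was 0.333 for loops, anchors and span, the smallest that this test allows for 2 libraries against 2, so it cannot pass 0.05 here. PETs also differed by a ratio of 3.44, and with every library thinned to 253502 PETs the ratio of loops was 1.94.

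Each H3K27ac anchor had 9.46 ± 0.323 partner anchors at day 0 and 17.5 ± 0.00352 at day 3 (SD, n = 2), but 9.16 ± 0.108 and 9.23 ± 0.115 after thinning. Of the day 3 PETs in consensus loops, 53.8% ± 0.301 joined anchors that were both called at day 0 as well. Another 37.1% ± 0.169 joined such an anchor to one called only at day 3, and 9.05% ± 0.132 joined a pair called only at day 3. Over consensus loops, which leave out loops inside a merged anchor, the span was 100.5 ± 1.45 kb at day 0 and 113.3 ± 1.25 kb at day 3, a difference of 12.8 kb. Among those between anchors called at both times, it was 102.5 ± 1.43 kb at day 0 and 108.8 ± 0.926 kb at day 3, a difference of 6.33 kb.

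ARID1A libraries listed 160816 ± 4579 loops, a ratio of 0.992 to H3K27ac at day 3, between 26316.5 ± 47.4 anchors covering 201.2 and 201.5 Mb (SD, n = 2). Here too the replicates list nearly the same anchors, so the SD of anchor number does not measure their spread. ARID1A loops held 2.81 ± 0.0620 PETs each, and 56.6% ± 0.585 of them rested on a single PET against 41.3% ± 0.336 for H3K27ac at day 3. Part of this goes with depth: after thinning, PETs per loop were 2.22 ± 0.00193 against 2.99 ± 0.0392, and 62.4% ± 0.00804 against 55.5% ± 0.214 of loops rested on a single PET. Contacts were shorter, with a span of 83.1 ± 0.241 kb, a difference of -17.4 kb from H3K27ac at day 3. The exact permutation p was 0.333 for the span (n = 2) and 1 for the number of loops. Among loops at the deposited value of 0.01 or less the span difference was -2.09 kb and the ratio of loops 0.725.

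**Figure D1:**
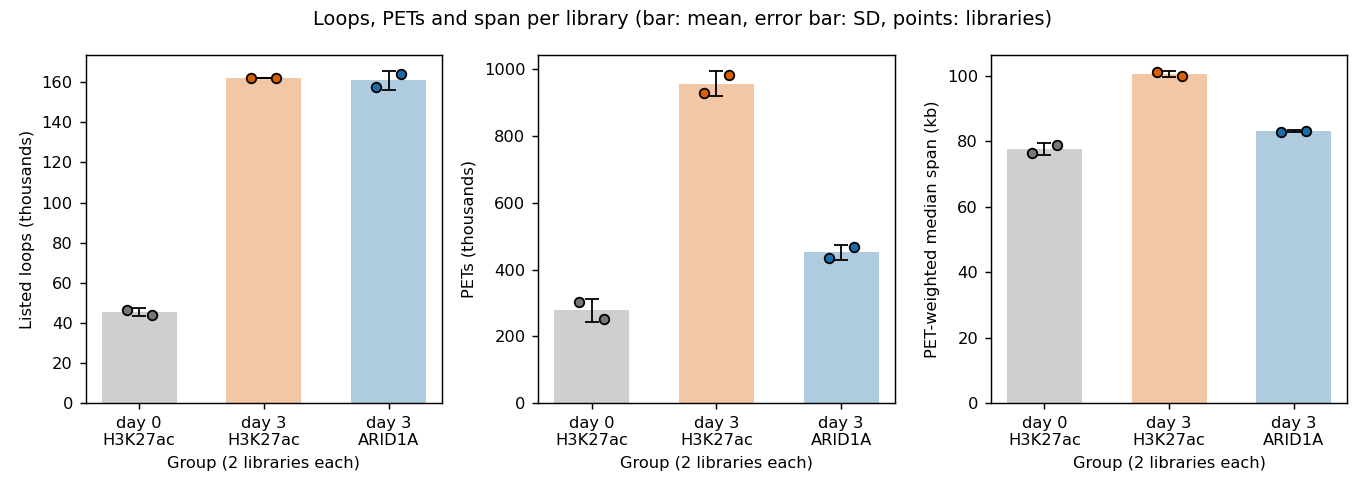
Listed loops, PETs and PET-weighted median span per library; bars are group means, error bars SD and points the 2 libraries of each group. The day 3 H3K27ac libraries hold 162010 and 162167 loops against 46677 and 44104 at day 0, and 929128 and 982141 PETs against 301703 and 253502.

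The comparison of H3K27ac at day 3 with day 0 asked which regions gained or lost contacts when SMARCB1 returned. Among anchors called at both times, counted contacts rose at 12q14.3 (hg19, chromosome 12, 65976658 to 66059233), from 498 ± 34.8 to 2202 ± 61.5 CPM. CPM are PETs scaled by the total of the library (SD, n = 2 per group), and the log2 fold change was 2.76 ± 0.08 (SE). The anchor was called over 13651 bp at day 0 and 75866 bp at day 3. Nearly all anchors named here differed in called width in the direction of their fold, as given below. Their folds therefore also count PETs in stretches called at 1 time only. A neighbouring pair in 2p16.1 also rose, by 3.91 ± 0.14 at 58854536 to 58895687 and by 2.29 ± 0.09 at 58778232 to 58853761. In 17q21.31 the anchors at 41767192 to 41817327 and at 41818552 to 41847801 rose by 3.23 ± 0.11 and 2.09 ± 0.11. Counted contacts fell at 15q26.1 (chromosome 15, 93408870 to 93476210), from 1368 ± 146 to 63.3 ± 9.60 CPM, a log2 fold change of -3.82 ± 0.13. That anchor was called over 49409 bp at day 0 and 4257 bp at day 3.

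Bands 8q24.21 and 14q24.1 held named anchors of both directions. In 8q24.21 the anchor at 127454430 to 127526119 fell from 5202 ± 99.99 to 649 ± 33.6 CPM (log2 fold change -2.38 ± 0.06), while those at 127612115 to 127644930 and 128857022 to 128892599 rose by 2.46 ± 0.15 and 2.55 ± 0.14. In 14q24.1 the anchor at 68704671 to 68738466 had a log2 fold change of -3.72 ± 0.12 and that at 69535191 to 69570823 one of 2.87 ± 0.15. The other anchors named as higher lay in 20q13.13, 4p14, 7p12.3 and 3q22.1, the last with 7 and 3 PETs at day 0 and 256 and 294 at day 3. The other anchors named as lower lay in 15q26.1, 5q13.3, 15q23, 1p34.3, 2p22.1, 3q13.31, 10q23.33, 19p13.11 and again 8q24.21. Over the 12 named as higher the fold lay between 3.06 and 22.4 with adjusted p up to 1.03e-38, and over the 12 named as lower between 2.13 and 14.1 with adjusted p up to 2.07e-35. An ARID1A anchor was called at 11 of the 12 in each direction.

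The same regions held the loops named by the rule. Every loop named as higher had an anchor called wider at day 3, and every loop named as lower had one called narrower. These folds too count PETs in stretches called at 1 time only. The loop between the 2p16.1 anchors, spanning 59.1 kb, went from 3 and 5 PETs at day 0 to 471 and 495 at day 3 (log2 fold change 5.58 ± 0.25). From the 12q14.3 anchor, the loop to 66105039 to 66143732 rose by 2.73 ± 0.15 and that to 65813661 to 65875701, over 173 kb, by 3.93 ± 0.24. The loop between the 17q21.31 anchors rose by 3.94 ± 0.24. In 15q26.1 the loop from 93339264 to 93408870 went from 377 and 271 PETs to 61 and 50 (log2 fold change -3.85 ± 0.13). Loops of the 8q24.21 anchor at 127454430 to its neighbours at 127383574 and 127554280 changed by -2.34 ± 0.08 and -2.79 ± 0.10, and the 14q24.1 loop from 68568464 to 68704671 by -3.91 ± 0.22. The largest adjusted p among these 8 loops was 3.26e-57, for the second 12q14.3 loop.

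**Figure D2:**
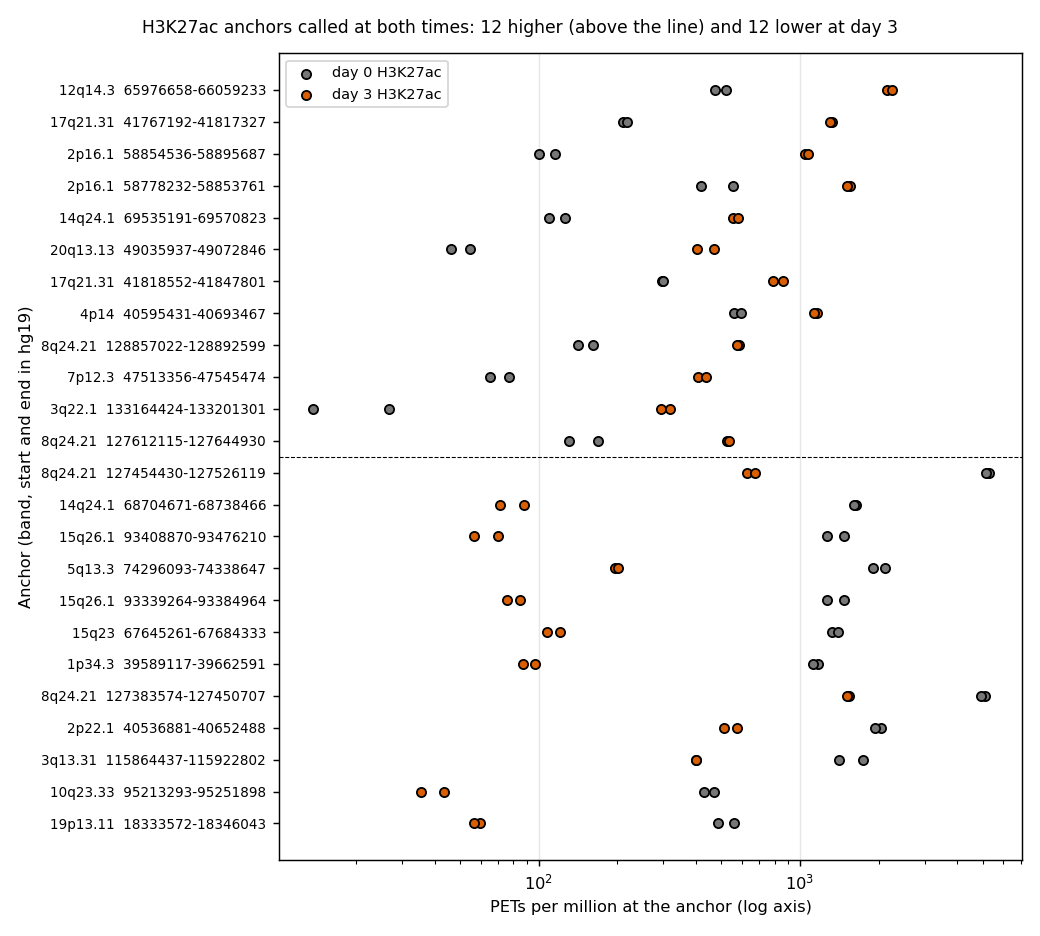
PETs in CPM (log axis) of each H3K27ac library at the 12 anchors named as higher at day 3, above the dashed line, and the 12 named as lower, all called at both times; each point is 1 library. At 3q22.1 the day 0 libraries held 7 and 3 PETs and the day 3 libraries 256 and 294; the log2 fold changes in the text are relative to the PETs of the tested set, and CPM to all consensus PETs, so they differ from ratios of these values.

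Of 6251 anchors called at both times, edgeR called 1294 higher and 1177 lower, and of 16642 loops between such anchors 1389 higher and 1115 lower. Scaled by library totals, which moved the median log2 fold change by -0.62 for anchors and -0.57 for loops, the split was 393 higher and 3436 lower anchors, and 577 higher and 3543 lower loops; the fold changes above, scaled by the PETs within this set, are thus relative to the typical anchor called at both times. Fewer loops were called without any 1 library: 1041 and 1227 without day 0 replicate 1 or 2 (51.2% and 48.4% higher), and 1361 and 1267 without day 3 replicate 1 or 2 (64.8% and 64.6% higher). Fold change went with how wide an anchor was called in the 2 groups (Spearman correlation 0.68 across 6251 anchors, which are not independent): the 15q26.1 anchor spanned 49409 bp at day 0 and 4257 bp at day 3, and the 2p16.1 anchor at 58854536 spanned 5785 and 38522 bp. All 12 anchors named as higher were called wider at day 3, by 3.43 to 9.19 times, and 10 of the 12 named as lower were called narrower, so these folds also count PETs in stretches called at 1 time only. With anchors of similar width, 20 of 1160 loops and 274 of 1675 anchors were called, against 2504 of 16642 loops and 2471 of 6251 anchors without this limit. Far fewer were tested, and the share called among those tested was lower too. After thinning to the smallest library, 47 of 9012 loops and 1540 of 5154 anchors were called. DESeq2 called 584 loops and 1182 anchors, and gave no adjusted p for 10002 loops and 849 anchors.

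Over all regions, those with no anchor at day 0 included, 22086 of 37920 loops were called higher and 3103 lower, as were 9762 and 2397 of 15046 anchors. Of the anchors called higher, 7854 (80.5%) had no anchor at day 0 and were not measured there, and 90.2% of the loops called higher lacked a day 0 anchor at 1 end or at both. Of those called lower, 20.6% of anchors had no day 3 anchor and 43.9% of loops lacked it at 1 end or at both. The first anchor named as higher was in 2p16.1 (58736084 to 58776716), next to the pair above, with 1541 and 1617 PETs at day 3 and no anchor at day 0; where a group has no anchor its 0 is set by anchor calling, so the call and its rank test no change in contacts. A further 8 of the 12 named as higher had no day 0 anchor, among them 40484969 to 40522326 in 17q21.2 (1074 and 1064 PETs), 1092960 to 1108814 in 19p13.3 and 36729940 to 36759985 in 6p21.2. All 12 named as lower had no day 3 anchor, led by 26180088 to 26239704 in 6p22.2 (1793 and 1501 PETs at day 0), 54635225 to 54701000 in 14q22.2 and 57872573 to 57939256 in 17q23.1. An ARID1A anchor was called at 9 of the 12 higher and 8 of the 12 lower.

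These totals depended on the libraries and the scaling. With library totals, 18903 loops were higher and 5712 lower. Without day 0 replicate 1 or 2, 7729 and 15681 loops were called. Without day 3 replicate 1 or 2, 2858 and 2795 loops were called, of which 34.8% and 34.1% were higher, and 3268 and 3231 anchors, of which 43.3% and 43.9% were higher, since a loop listed only at day 3 then reached 4 PETs in 1 library alone. With anchors overlapping reciprocally by 90%, edgeR called 0 of 179 loops and 0 of 163 anchors (15 and 21 at an unadjusted p under 0.05).

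The comparison of ARID1A with H3K27ac at day 3 asked where contacts of the SWI/SNF complex and of the active mark differ in the same cells. The antibodies differ, so a fold is a difference in share of contacts and not in amount of protein. Nearly all anchors named here differed in called width too, as given below, so folds also count PETs in stretches called with 1 antibody only. Among anchors called with both, ARID1A contacts were higher at a pair in 17q21.33 (chromosome 17), at 49074824 to 49115164 with 43.8 ± 11.2 CPM for H3K27ac and 576 ± 26 for ARID1A (SD, n = 2 per group; log2 fold change 4.37 ± 0.14), and at 49141970 to 49177788 (4.05 ± 0.14). ARID1A was also higher at 4q22.1 (90635813 to 90664308, 4.13 ± 0.16), 15q26.1 (93408870 to 93476210, 3.63 ± 0.13), 6q25.2 (154932757 to 154963788, 3.50 ± 0.13) and 3p14.3 (57792837 to 57857500, 2.50 ± 0.09). It was lower at 20q13.2 (52343804 to 52395921), with 2682 ± 55.3 CPM for H3K27ac and 261 ± 19.2 for ARID1A (-2.70 ± 0.08), at 9q33.3 (129372161 to 129400338, -4.05 ± 0.14) and at a pair in 6p22.1 (27847213 to 27866332, -4.90 ± 0.18, and 27771845 to 27811500, -2.95 ± 0.10).

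In 17q21.2, 3 neighbouring anchors between 40525853 and 40692490 were all lower for ARID1A, with log2 fold changes of -1.88 ± 0.07, -3.29 ± 0.10 and -2.23 ± 0.09. The other anchors named as higher lay in 2p22.1, 1p34.3, 3q25.1, 12q23.3 and 14q24.1, and the other anchors named as lower in 17p11.2, 9q34.11, 2p21, 2q23.3 and again 20q13.2. Over the 12 named as higher the fold lay between 3.35 and 20.7 (adjusted p up to 6.48e-131), and over the 12 named as lower between 3.29 and 29.8 (adjusted p up to 1.00e-111). All 12 named as lower had a day 0 H3K27ac anchor, as did 7 of the 12 named as higher.

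The 15q26.1 loop from 93339264 to 93408870 was lower for H3K27ac at day 3 than at day 0. It held 194 PETs in each ARID1A library against 61 and 50 for H3K27ac at day 3 (log2 fold change 3.45 ± 0.15). The same day 3 H3K27ac libraries enter both comparisons. The anchor at 93408870 was called over 49409 bp at day 0, 4257 bp for day 3 H3K27ac and 66633 bp for ARID1A. Both differences therefore also count PETs in stretches not called for H3K27ac at day 3. ARID1A was also higher for loops in 3p14.3 (57757852 to 57792837, 3.75 ± 0.17) and 12q23.3 (107379679 to 107442095, 4.60 ± 0.23). The 17q21.33 loop from 49074824 to 49117371 held 139 PETs over the ARID1A libraries and 2 over those of H3K27ac, a ratio of 143 on the CPM scale with a 95% counting interval of 38.8 to 1192. ARID1A was lower for the 17q21.2 loop from 40525853 to 40591807 (-4.19 ± 0.23) and for 20q13.2 loops from 52343804 to 52397231 (-4.17 ± 0.24) and to 52502666 (-3.56 ± 0.21). The 6p22.1 loop from 27771845 to 27847213 held 905 PETs for H3K27ac and 3 for ARID1A, a ratio of 147 with an interval of 50 to 712. After thinning to the smallest library, all 8 of these named loops lost significance, but there edgeR called 0 of all 9664 loops tested. With its newer quasi-likelihood method on the same thinned counts, 1207 loops were called and these 8 kept significance.

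**Figure D3:**
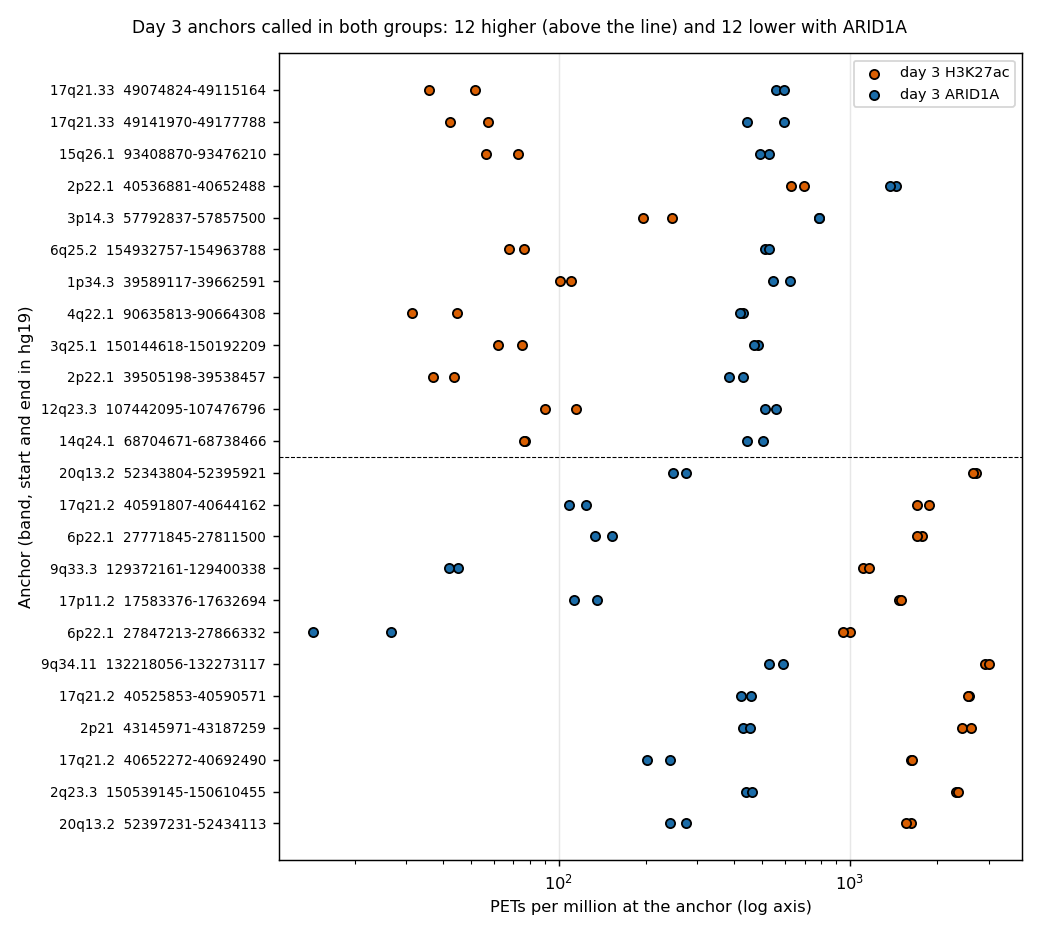
PETs in CPM (log axis) of each day 3 library at the 12 anchors named as higher with ARID1A, above the dashed line, and the 12 named as lower, all called with both antibodies; each point is 1 library. At 20q13.2 (52343804) H3K27ac libraries average 2682 and ARID1A libraries 261; the log2 fold changes in the text are relative to the PETs of the tested set, not to all consensus PETs as CPM are.

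Of 11052 anchors called with both antibodies, edgeR called 3477 higher and 3597 lower for ARID1A, and of 28338 loops 4118 higher and 5314 lower. Scaled by library totals, which moved the median by -0.65 and -0.61, there were 1767 higher and 5972 lower anchors, and 2583 higher and 10488 lower loops. Without H3K27ac replicate 1 or 2, 4152 and 4086 loops were called, and without ARID1A replicate 1 or 2, 4027 and 3866, of which 57.5% and 53.9% were higher; DESeq2 called 2271 higher and 1412 lower. Anchor width moved with the fold here too (Spearman correlation 0.67 across 11052 anchors): the 17q21.33 anchor at 49074824 spanned 5537 bp for H3K27ac and 40340 bp for ARID1A. All 12 named as higher were called wider for ARID1A, by 2.72 to 15.7 times, and 11 of the 12 named as lower narrower. With anchors of similar width, 290 of 2468 loops and 1450 of 2835 anchors were called, against 9432 of 28338 loops and 7074 of 11052 anchors without this limit. After thinning to the smallest library, edgeR called 0 of 9664 loops, or 1207 with its newer quasi-likelihood method, and 4077 of 7615 anchors.

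Over all regions, 14062 of 47562 loops were called higher and 15760 lower for ARID1A, and 12139 and 7472 of 22850 anchors. No H3K27ac anchor was called at 66.0% of the higher anchors and no ARID1A anchor at 43.0% of the lower. The 12 named as higher all lacked a day 3 H3K27ac anchor, while 9 of them had one at day 0, among them 54635225 to 54701000 in 14q22.2 (557 and 555 ARID1A PETs) and 57872573 to 57939256 in 17q23.1 (462 and 494). A pair in 15q22.31 (67119711 to 67158387 and 67159610 to 67198308) had an ARID1A anchor and none for H3K27ac at either time. The 12 named as lower all lacked an ARID1A anchor, led by 68568464 to 68617187 in 14q24.1 (2287 and 2309 H3K27ac PETs) and 25881214 to 25912056 in 7p15.2.

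With library totals, which moved the median of loops by -0.61 and of anchors by -0.23, 12310 loops were higher and 20849 lower. The balance turned with DESeq2 (12527 higher and 8347 lower), with no filter (23375 and 4849) and with the replicate block (12909 and 7820). It also turned for loops listed in every library (3369 and 2692) and after thinning (4340 and 2409). After thinning with library totals it did not turn (3067 and 3350). Without H3K27ac replicate 1 or 2, 14687 and 14489 loops were called, 81.9% and 82.6% of them higher. Without ARID1A replicate 1 or 2, 6918 and 6671 loops were called, 33.6% and 34.6% of them higher, and 10519 and 10504 anchors, 34.5% and 34.1% of them higher. The 90% overlap left 19 called loops and 53 called anchors.

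Fold change varied with span, and its sign depended on the scaling. Among loops between anchors called with both antibodies, ARID1A against H3K27ac had a median log2 fold change of 0.23 under 20 kb (543 called higher and 358 lower of 1844 loops), -0.47 from 100 to 250 kb and -1.81 from 1000 to 2000 kb (6 higher and 243 lower of 994). For H3K27ac at day 3 against day 0 the medians were -0.24 under 20 kb (66 higher and 119 lower of 564), 0.06 from 100 to 250 kb and 0.38 from 1000 to 2000 kb (55 higher and 30 lower of 1042). With library totals all medians shift, by -0.61 and -0.57, which turns every positive median named here negative and keeps the order of the spans. Loops had to hold 4 or more PETs in at least 2 libraries, and the day 3 H3K27ac libraries were the deepest. Loops with few PETs can thus enter through these libraries alone, which can move medians of long spans towards them. Over all listed loops, spans of 1000 to 2000 kb held 4.32% of PETs for day 0 H3K27ac, 5.80% for day 3 H3K27ac and 3.96% for ARID1A. The size of the medians at long spans therefore does not measure the change in long contacts.

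**Figure D4:**
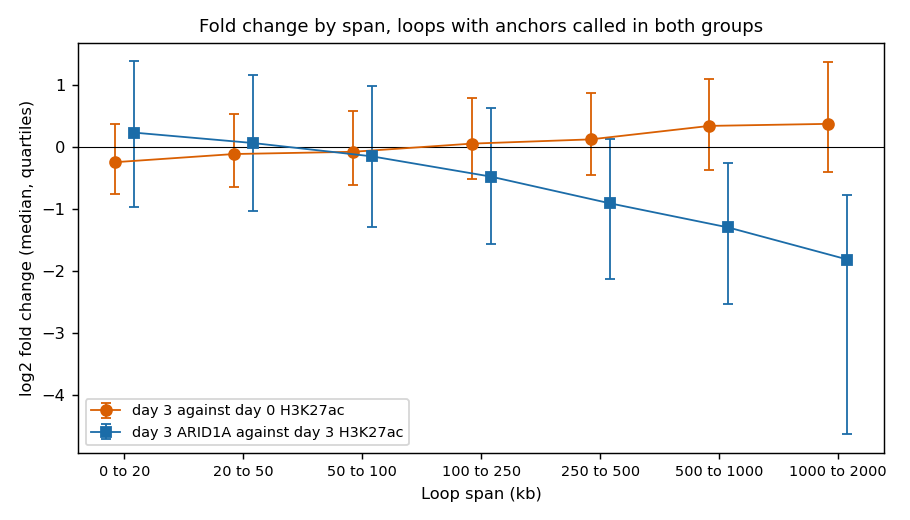
Median log2 fold change (points) and quartiles (bars) of loops by span class in kb, for loops between anchors called in both groups compared. Loops with few PETs can pass the filter through the deeper day 3 H3K27ac libraries alone, which can move medians of long spans towards these. The ARID1A medians go from 0.23 to -1.81 and the H3K27ac day 3 against day 0 medians from -0.24 to 0.38; scaling by library totals would shift all points by -0.61 and -0.57 and make the positive ones negative.

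Whether regions that gain H3K27ac contacts are those where ARID1A is found was the question of the next comparison. Of the regions called as H3K27ac anchors only at day 3, 6516 of 9185 (70.9%, 95% Wilson interval 70.0 to 71.9) also held an ARID1A anchor, against 5797 of 6990 called at both times (82.9%, 82.0 to 83.8) and 267 of 668 called only at day 0 (40%, 36.3 to 43.7). The share at day 3 only was above that at day 0 only (Fisher's exact p = 3.04e-57) and below that at both times (p = 6.98e-72). Anchors called at both times were also wider, with a median H3K27ac width of 7.73 kb against 5.07 kb at day 3 only and 5.26 kb at day 0 only. Within 6 classes of that width, chosen after the data were examined, the odds ratio of day 3 only against both times was 0.727 (95% interval 0.669 to 0.789) and against day 0 only 3.97 (3.36 to 4.69). ARID1A also had 13158 anchors with no H3K27ac anchor, of 25738. Among anchors called at both times, 1199 of the 1294 with higher contacts at day 3 held an ARID1A anchor (92.7%, 91.1 to 94.0), against 974 of the 1177 with lower contacts (82.8%, 80.5 to 84.8) and 3140 of the 3780 not called (83.1%, 81.8 to 84.2). The higher anchors differed from the lower (Fisher's exact p = 3.63e-14), and no difference was detected between the lower and those not called (p = 0.79). Higher anchors were also wider, with a median of 17.2 kb against 9.22 kb for those not called.

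For loops, both ARID1A libraries listed 11001 of the 22086 H3K27ac loops higher at day 3 (49.8%, 49.2 to 50.5), 1462 of the 3103 lower (47.1%, 45.4 to 48.9) and 5848 of the 12731 not called (45.9%, 45.1 to 46.8). Higher minus lower was 2.69 percentage points (95% interval 0.818 to 4.57; Fisher's exact p = 0.00512), and higher minus not called 3.88 points (p = 3.42e-12). With anchors called in both H3K27ac groups, a set chosen after the data were examined, they listed 1014 of 1389 higher loops (73.0%), 661 of 1115 lower (59.3%) and 6639 of 14138 not called (47.0%), and higher minus lower was 13.7 points (10 to 17.4; Fisher's exact p = 4.69e-13). Asking for 4 or more PETs in both ARID1A libraries turned the first difference to -5.60 points, and with anchors called in all 3 groups it was 2.05 points (Fisher's exact p = 0.235). Without ARID1A replicate 1 or 2, the first difference was 4.90 and 4.89 points and the second 0.224 and 0.532, which then no longer passed the test.

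Replicates were compared by the loops they shared. The 2 day 0 H3K27ac libraries shared 55.1% of the loops that either listed, the 2 at day 3 55.5% and the 2 ARID1A libraries 38.9%. With every library thinned to 219827 PETs between consensus anchors these shares were 54.3%, 39.9% and 32.4%. Single ARID1A loops were the least shared at either depth.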

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

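Tests with anchors called in both groups, of similar width or overlapping by 90% were chosen only after the results were seen. So were those with the newer quasi-likelihood method, with the day 3 H3K27ac libraries summed as 1, and with thinning and library totals together. The set with anchors in all 3 groups was added after the data were examined but before its result. The other alternatives of the fits were fixed before the data were examined. Over all totals, 92 alternative values kept their direction and side of the threshold or lay within 1.5 times, 83 moved further, 5 reversed, 3 were stronger and 4 weaker. Of 1673 values for the named anchors and loops, 1665 kept direction and significance, 8 lost significance and 0 reversed. The 8 were loops of ARID1A against H3K27ac after thinning, where edgeR called 0 of 9664 loops. They kept significance with the newer quasi-likelihood method on the same thinned counts. Named anchors and loops have the smallest p in these same libraries, and over all regions most of them lack an anchor in 1 group. Few losses or reversals are therefore built in, and the tally does not measure robustness. Values are missing where the alternatives are hardest: of the 32 named per comparison in each set, similar width still tested 1 and 2 and 90% overlap 0, listing in every library 4 and 0, and leaving out a library 16 to 20 over all regions, so these counts say little of them. For single loops most 2-fold changes were missed in simulation, where only 200 loops were changed. Causes were not tested, except that fewer PETs, loops or libraries are tested by construction. Similar width left 1160 loops and 1675 anchors to test for day 3 against day 0 H3K27ac, and 2468 and 2835 for ARID1A against H3K27ac. In each of these the share called was also lower than over all anchors called in both groups.

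For day 3 against day 0 H3K27ac, the 25189 called loops became 10461 with DESeq2 (4997 of 37920 without an adjusted p), 15215 with no filter, 10818 with the stricter filter, 5971 after thinning (5197 with library totals, 2934 of them higher), 8651 at a deposited value of 0.01 or less, 2092 if listed in every library (1023 higher and 1069 lower), 2504 with anchors called in both groups and 0 by edgeR with 90% overlap (15 of 179 at an unadjusted p under 0.05); leaving out a library gave 2795 to 15681. The 12159 anchors became 6433 after thinning (6462 with library totals), 5333 at a value of 0.01 or less, 2157 if listed in every library, 2471 with anchors in both groups and 0 by edgeR with 90% overlap (21 of 163 unadjusted); leaving out a library gave 3231 to 11152. With anchors in both groups, the 2504 loops became 4120 with library totals, 584 with DESeq2 (which gave 10002 of 16642 no adjusted p), 47 after thinning (78 with the newer method) and 20 with similar width, or 1041 to 1361 without a library. The 2471 anchors became 3829 with library totals, 1182 with DESeq2 (849 of 6251 without an adjusted p), 1540 after thinning (1553 with the newer method) and 274 with similar width, or 1792 to 1867 without a library.

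For ARID1A against H3K27ac, the 29822 loops became 11763 with the stricter filter, 6749 after thinning (6417 with library totals, 3067 of them higher), 12570 at a value of 0.01 or less, 6061 if listed in every library (3369 higher and 2692 lower), 45785 in 10 kb bins, 9432 with anchors in both groups and 19 with 90% overlap, or 6671 to 14687 without a library. The 19611 anchors became 11164 after thinning (11168 with library totals), 8648 at a value of 0.01 or less, 5196 if listed in every library, 7074 with anchors in both groups and 53 with 90% overlap, or 10504 to 15035 without a library. With anchors in both groups, the 9432 loops became 3683 with DESeq2, 5584 with the stricter filter, 290 with similar width and 0 by edgeR after thinning (3595 at an unadjusted p under 0.05; 1207 with the newer method), or 3866 to 4152 without a library. The 7074 anchors became 4077 after thinning (4117 with the newer method) and 1450 with similar width, or 5212 to 5851 without a library.

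The ratio of loops, 3.57 at day 3 against day 0, was 1.94 after thinning, 3.88 at a value of 0.01 or less and 3.47 to 3.68 without a library. For ARID1A, 0.992 became 1.35, 0.725 and, for loops of 4 PETs or more, 0.571, or 0.972 to 1.01 without a library. The span difference of 22.8 kb was 20.1 kb at a value of 0.01 or less, 15.1 kb for 4 PETs or more and 21.6 to 24.1 kb without a library. For ARID1A, -17.4 kb became -2.09 kb, -30.4 kb and -18.0 to -16.8 kb. Shared loops of replicates, 55.1%, 55.5% and 38.9%, were 63.0%, 62.1% and 51.9% for 4 PETs or more and 54.3%, 39.9% and 32.4% after thinning.

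For loops listed in the ARID1A libraries, higher minus lower was -5.60 points for 4 PETs or more, 5.24 with anchors within 5 kb, 1.64 in 10 kb bins, 13.7 with anchors in both H3K27ac groups, 2.05 in all 3 and 4.89 to 4.90 without an ARID1A library. Higher minus not called was 5.75 points for 4 PETs or more, 3.63 with anchors within 5 kb, 0.746 in 10 kb bins, 26.04 with anchors in both H3K27ac groups, 23.7 in all 3 and 0.224 to 0.532 without an ARID1A library. Lower minus not called, 1.18 points (Fisher's exact p = 0.244), was 11.3 for 4 PETs or more, -0.895 in 10 kb bins, -1.61 with anchors within 5 kb, 12.3 with anchors in both H3K27ac groups, 21.7 in all 3, and -4.68 to -4.36 without an ARID1A library.

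Whether replicate numbers pair the libraries could not be told. Differences between replicates 1 and 2 correlated between groups at 0.0145 and 0.00542 for day 3 against day 0 (loops and anchors). For ARID1A against H3K27ac the correlations were -0.0182 and 0.0137. Replicates differed by little more than counting noise per loop, so weak correlations would arise with or without pairing. With the replicate number as a block, 10938 loops and 12007 anchors were called for day 3 against day 0, and 20729 (12909 higher and 7820 lower) and 19631 for ARID1A against H3K27ac. With the day 3 H3K27ac libraries summed as 1, 18696 loops and 11984 anchors were called for day 3 against day 0. Alternatives on promoter windows, genes and gene lists were not run, since no annotation of hg19 was used here.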

Other observations

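The tests by cytoband and by anchor width, those on anchors called in both groups, on day 3 PETs and on thinning with library totals were chosen only after the result was seen, as was the use of thinning and the deposited value, fixed beforehand as alternatives, as tests here; the set with anchors in all 3 groups was added after the data were examined but before its result.

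Called H3K27ac anchors of the same direction lay together in some cytobands. Part of this is built in, since each PET counts at both anchors of its loop and neighbouring anchors share PETs. The day 0 libraries also differed from each other over windows of 1 Mb by more than counting noise (chi-square over degrees of freedom 1.36). Among called anchors present at both times, all 15 in 1p31.3, 12 in 14q32.2, 12 in 4p14, 11 in 9p24.2 and 10 in 2p16.1 were higher at day 3, as were 14 of 15 in 7q21.11, against about 52.1% elsewhere. In 19q13.42 0 of 18 were higher (95% Wilson interval up to 17.6%), in 1q22 0 of 16 and in 11q13.1 1 of 20. Of 63 bands tested, 16 differed from the rest by Fisher's exact test after Benjamini-Hochberg adjustment (7 above and 9 below; adjusted p from 9.37e-05 to 0.034); anchors in a band are not independent, and the split moves with the scaling. For ARID1A against H3K27ac, 139 of 287 bands differed: 34 of 34 called anchors in 3q26.31, 28 of 28 in 7q21.11 and 26 of 26 in 2p22.1 were higher, against 0 of 45 in 16p13.3 and 7 of 81 in 19p13.3. Day 3 H3K27ac anchors without a day 0 anchor made up 19 of 20 in 7q31.1 and 26 of 29 in 5q21.3 but 17 of 59 in 19q13.33 and 5 of 24 in 6p22.2 (5 of 344 bands past the threshold). In 4q22.1, 61 of 82 ARID1A anchors (74.4%) lacked an H3K27ac anchor at day 3, against 52.1% elsewhere (adjusted p = 0.0239), the only such band of 463.

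Day 0 H3K27ac anchors without one at day 3 varied with width. They made up 9.49% of 2793 anchors under 5 kb, 9.75% of 3374 of 5 to 10 kb, 2.87% of 975 of 10 to 20 kb, 6.38% of 298 of 20 to 30 kb, 7.87% of 127 of 30 to 40 kb and 17 of 91 of 40 kb or more (18.7%, 95% Wilson interval 12 to 27.9). The widest differed from all narrower ones (8.60% of 7567; Fisher's exact p = 0.0022, 1 of 12 such tests, unadjusted). An ARID1A anchor was called at 14 of those 17, which is about the share for this width, as only 13 of all 91 lacked one (14.3%). In the opposite direction, 3 of 171 day 3 anchors of 40 kb or more had no day 0 anchor (1.75%), against 57.4% of all 16004 narrower ones, a share that fell with each width class.

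More H3K27ac loops were higher than lower at day 3, 87.7% of those called. With anchors called in both groups the share was 55.5%, but 14.0% with library totals: the scaling sets this share, so the separate calling of anchors cannot be told apart from a gain of anchors. After thinning the share was 72.5%, but 56.5% with library totals, so the depth of the PET counts is not excluded either. Of the loops called higher, 90.2% lacked a day 0 anchor at 1 end or at both, which may come from anchor calls at unequal depth. A biological gain of new anchors with SMARCB1, doxycycline or time also stays open, as untested here.

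Loops higher at day 3 were listed in the ARID1A libraries more often than loops lower at day 3, by 2.69 points, and by 13.7 with anchors in both H3K27ac groups, but less often, by -5.60 points, if 4 or more PETs are asked for in both ARID1A libraries. Where anchors were called in all 3 groups the difference was 2.05 points (95% interval -1.36 to 5.45); this interval holds both 0 and 2.69, so the calling of ARID1A anchors at one set of loops stays open. Strata of PET number and span over all 4 H3K27ac libraries left an odds ratio of 1.94 (1.78 to 2.12), or 2.41 (1.77 to 3.28) with anchors in all 3 groups, which argues against these as the whole source, but such strata leave day 3 PETs uneven. In strata of day 3 PETs and span it was 1.11 (1.02 to 1.20), 1.02 (0.910 to 1.15) in finer classes and 0.973 (0.856 to 1.11) above 15 PETs, and in the first strata 1.60 (1.32 to 1.94) with anchors in both H3K27ac groups and 0.867 (0.638 to 1.18) in all 3, so the answer turns on the strata and the set, and the strength of a loop at day 3 stays open. Recruitment of ARID1A to gained contacts stays open, since ARID1A was measured here only at day 3.

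ARID1A contacts were shorter than H3K27ac contacts at day 3, by a span difference of -17.4 kb. Anchors called in both groups gave -24.0 kb (-23.8 kb over all consensus loops), which argues against different anchor sets. Thinning gave -16.9 kb, but random thinning cannot move a median over PETs by much, so depth stays open. Among loops at the deposited value of 0.01 or less the difference was -2.09 kb, so loops above that value may carry most of it. Loops of 4 PETs or more gave -30.4 kb, and how the value was computed is not given in the sources used here, so this stays open, as does a biological difference in reach.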
